A study of Mus musculus with 4 samples.

How the data were processed

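Spleen cells of aged mice were sorted as live CD45+ CD3+ CD19- cells and run on the 10x Genomics 5' v2 chemistry with T cell receptor enrichment, per the labels' protocols. The series has 4 samples: 1 expression library and 1 receptor library for each of 2 genotypes, grouped by their titles. The deposited counts are raw UMI counts per gene and barcode, made with Cell Ranger 6.1.2, per the file headers and the submitters' processing notes, which name the mm10 build. The deposited receptor tables give read and UMI counts per contig, the number of barcodes per clonotype and the fraction of barcodes in each clonotype, which was not used beyond a check against the counts. The values show that barcodes had been called as cells and contigs kept as productive and of high confidence before deposit; the version of the receptor step is not given in the sources used here. Gene symbols were taken from the 32285 features of the files, and the position of Ighm from the RefSeq table of the same build. A PCR-amplified contig read is not an independent molecule, and intervals cover counting error only.

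Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 15 WT and 18 KO barcodes for genes and 69 and 116 for mitochondrial UMIs, and left 8925 and 8185 cells. Scrublet, as in scanpy 1.11.5, called 0 doublets in each library where 7.20% and 6.65% were assumed, so it did not work and no doublet was removed; cells with more than 1 TRB chain (6.82% and 5.45% of cells with a TRB chain) were left out in an alternative instead. Such cells can also be single cells with a pair of rearranged chains. Both libraries were clustered together on log-normalized counts scaled to 10000, with 2000 variable genes (receptor, immunoglobulin, mitochondrial, ribosomal and sex-linked genes left out), 30 principal components, 15 neighbours and Leiden resolution 1 in igraph 0.11.9, without integration. After a look at the clusters the neighbour search was replaced by an exact one on rounded components, so that repeated runs give the same clusters. Clusters were named from 21 marker sets, where leading genes allowed it. The memory CD4 T-like cluster also had the stress gene Hspa1a among its leading genes. Cluster 8 (median 924 and 918 UMIs in WT and KO) and cluster 15 (1092 and 1204.5) were shallow and stayed unnamed among the T cells. Myeloid-like, neutrophil-like and mixed antigen-presenting (cluster 14) cells were left out of the T cell sums.

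UMIs were summed per library over all T cells, over the CD4 and CD8 gates and within classes of at least 100 cells in both libraries. The gates rest on at least 1 UMI of Cd4, or of Cd8a or Cd8b1, and so depend on depth: the CD4 gate held 3229 WT and 949 KO cells (16905388 and 4804338 UMIs), and the CD8 gate 3158 and 5258 cells (24694801 and 37913448 UMIs). Differences are log2 ratios of CPM, KO over WT, with conditional-binomial intervals; CPM levels have exact Poisson and shares Clopper-Pearson intervals. Named genes were those with at least 100 UMIs in a library and 20 CPM in either, the 12 highest and 12 lowest per comparison (5 and 5 within a class), with receptor, immunoglobulin, mitochondrial, ribosomal protein, sex-linked and unnamed-locus genes left out, plus leading members of 29 fixed lists and 8 fixed genes. A list's members count as measured at a mean of 5 CPM, and its median was placed among 10000 random lists of the same size from 20 expression bins; a member at 0 in a library took 3 UMIs there. A member counts as higher or lower when it lay at least 1.25 times above or below the median of all genes. The gene lists, markers, gates, named-gene rule and most alternatives were set before the data were examined. Most tests of explanations were chosen afterwards, as stated under Other observations.

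Clonotypes are those of the submitters, counted over cells with a TRB chain, unless stated otherwise. Expansion was compared after drawing the same number of cells from each library (mean of 100 draws), and clonotype sizes were counted among the drawn cells. Intervals of drawn shares are Clopper-Pearson intervals of the mean count over the draws, rounded to whole cells. Intervals of clonal shares take cells as independent and do not allow for cells of a clone entering together. V gene use was taken from cells with 1 chain of the locus. TRBV shares and CDR3 lengths over clonotypes count each different TRB chain once. TRAV shares over clonotypes count each TRA chain once per clonotype of the submitters. Cells were joined to expression by barcode.

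On simulated counts with the real means and library sizes (10624 genes over all barcodes), the interval excluded 0 on the right side for 91.5%, 99.5%, 100% and 100% of 200 genes changed by 1.25, 1.5, 2 and 4 times. The intervals held the true ratio for 95.1%, 95.4%, 95.5% and 95.2% of genes. The simulated counts were independent Poisson draws, for which such intervals hold by design. UMIs that cluster within cells or clones were not simulated. These shares therefore check the calculation and not the spread in the real libraries. At 4 times, 37.6% of unchanged genes lay off 0 because the total itself moved, a property of every CPM ratio here. A list of 15 raised genes reached percentile 100 at each size, and drawing cells from known clones gave 19.6% where 19.6% was computed exactly. Alternatives covered filters, receptor-carrying cells, thinning to 1000 UMIs (389 WT and 216 KO T cells were shallower), gates, clustering settings, TMM factors of edgeR 4.0.16 in R 4.3.3, median-of-ratios factors, low-count filters, weighting of cells and clonotype definitions. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.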

Results

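The data set held droplet-based RNA counts and matched T cell receptor sequences of T cells sorted from the spleens of aged mice. Mice of 22 months that carry the µMT mutation, which disrupts the membrane form of the IgM heavy chain and leaves mice without mature B cells, were set against wild-type mice of the same age. Each genotype had 1 expression library and 1 receptor library, and the labels do not give the number of mice behind a library. No difference below therefore has a replicate check, and no test was possible. Brackets give exact 95% intervals that cover counting error only, except for draws of cells and for the tests under Other observations. The WT expression library held 55032870 UMIs in 8999 barcodes and the KO library 52997095 in 8312 barcodes. After filtering, 8718 WT and 7803 KO T cells remained, with medians of 5164.5 and 6235 UMIs per cell. A productive TCR beta chain (TRB) was found in 7159 WT and 5987 KO barcodes.

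B cell transcripts were far lower in the KO library. Igkc, the kappa light chain, stood at 135 CPM (counts per 1000000 UMIs; 132 to 138) in WT and 2.29 CPM (1.90 to 2.73) in KO kept cells. Cd79a, part of the B cell receptor complex, stood at 16 and 0.284 CPM. Cd19 had 101 UMIs in WT and none in KO, at least 32.4-fold lower with 3 UMIs taken as the limit of a count of 0. Ms4a1, which encodes CD20, was at least 86.2-fold lower on the same basis. Cells with B cell transcripts made up 55 of 8925 WT cells (0.616%, 0.465 to 0.801) and 1 of 8185 KO cells. Ighm, the targeted gene (chromosome 12, 113418826 to 113422730 in mm10), was at 317 CPM (312 to 322) in WT and 112 CPM (109 to 115) in KO. Counts from the 5' end of transcripts do not measure the deleted membrane exon, so Ighm itself checks nothing here; in the CD8 gate it was 114 and 110 CPM. All samples carry the same wild-type genotype entry in their labels, and the sample titles alone tell the genotypes apart.

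The balance of CD4 and CD8 T cells differed between the libraries. Cells with Cd4 and no Cd8a or Cd8b1 UMIs (the CD4 gate) were 37% (36.0 to 38.1) of WT T cells and 12.2% (11.4 to 12.9) of KO T cells. Cells with Cd8a or Cd8b1 and no Cd4 UMIs (the CD8 gate) were 36.2% (35.2 to 37.2) in WT and 67.4% (66.3 to 68.4) in KO. The ratio of CD4 to CD8 gate cells was 1.02 in WT and 0.180 in KO. The remaining 26.7% of WT and 20.5% of KO T cells had neither or both. With each cell thinned to 1000 UMIs, the CD4 gate held 16.8% and 4.88% of cells and the CD8 gate 30.6% and 51.0%.

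Naive cells took a larger share of KO T cells, and helper, regulatory and follicular helper cells a smaller one. Naive CD8 T-like cells were 7.49% (6.95 to 8.06) of WT and 32.4% (31.4 to 33.5) of KO T cells. Naive CD4 T-like cells were 5.98% (5.49 to 6.49) and 13.2% (12.4 to 14). Follicular helper T-like cells, the class that helps B cells in germinal centres, numbered 1332 in WT (15.3%, 14.5 to 16.1) and 27 in KO (0.346%, 0.228 to 0.503). Regulatory T-like cells, marked by the transcription factor Foxp3, were 14.7% (14 to 15.5) and 2.74% (2.39 to 3.13), and memory CD4 T-like cells 11.7% (11.1 to 12.4) and 3.19% (2.81 to 3.61). Memory CD8 T-like cells were 14.6% (13.9 to 15.3) in WT and 18.2% (17.4 to 19.1) in KO. Their gap of 3.65 percentage points was 0.801 points at a finer clustering. The follicular helper gap of -14.9 points was -23.5 at a coarser one. No cluster took the memory CD4 T-like name there, so that value may include cells of that class.

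**Figure D1:**
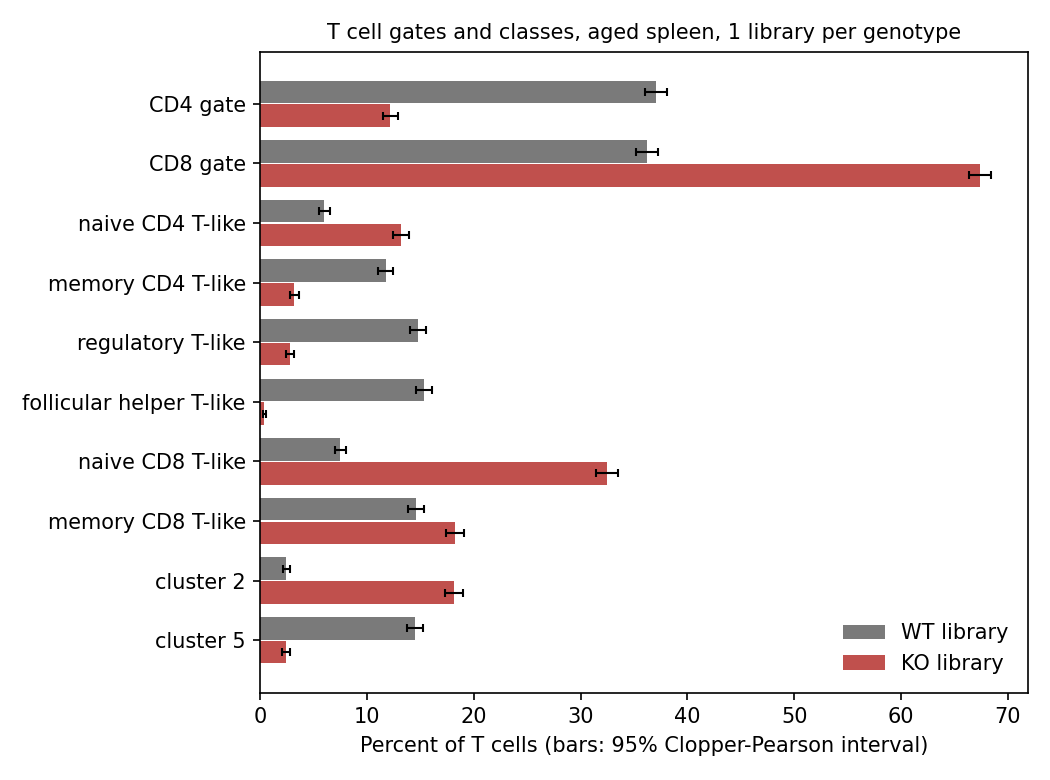
Share of T cells (horizontal axis, percent) in each gate, class or unnamed cluster (vertical axis) in the WT library (grey) and the KO library (red), with 95% Clopper-Pearson intervals as error bars. The CD8 gate and naive CD8 T-like bars are longer in KO (67.4% and 32.4%), and the CD4 gate, regulatory and follicular helper bars longer in WT (37%, 14.7% and 15.3%).

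Shares within each gate, which do not depend on the CD4 to CD8 balance, differed as well. Naive CD4 T-like cells were 9.79% (8.78 to 10.9) of the WT and 58.0% (54.7 to 61.1) of the KO CD4 gate. Follicular helper T-like cells were 33.1% (31.5 to 34.7) and 2.32% (1.46 to 3.49) of it, regulatory T-like cells 20.7% and 10.0%, and memory CD4 T-like cells 20.4% and 16.2%. In the CD8 gate, naive cells were 20% (18.6 to 21.4) in WT and 46.7% (45.3 to 48.1) in KO, and memory cells 38.4% and 25.7%. Cluster 2, led by natural killer receptor genes, held 2.42% of WT and 18.1% of KO T cells. Cluster 5, led by Gzmk, Ccl3 and Ccl4, held 14.5% and 2.40%. Natural killer T-like cells were 1.89% and 1.18%, interferon-responding T-like cells 1.80% and 1.22%, and cycling T-like cells 0.964% and 0.564%. Of the other unnamed clusters, cluster 8 held 3.38% and 3.69%, cluster 11 1.75% and 1.29%, cluster 13 1.86% and 0.756%, and cluster 15 had 109 and 50 cells. Cluster 17 had 37 WT cells and none in KO, which allows up to 0.0473% by the interval. A cluster drawn mostly from 1 library may be that library rather than a cell type, and the rebuilt names may differ from those of the study.

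Across all T cells, genes of exhausted, follicular helper and regulatory cells were lower in the KO library, and natural killer receptor genes were higher. The lowest were Il21, the cytokine of follicular helper cells (23.7 CPM in WT and 0.176 in KO, log2 ratio -7.07, -8.20 to -6.14), Sostdc1 (-6.54) and Lag3, an inhibitory receptor (117 and 2.41 CPM, -5.60, -5.87 to -5.34). Gzmk, the granzyme of age-associated T cells, was at 144 CPM in WT and 9.94 in KO (-3.86, -3.99 to -3.73), and Pdcd1, which encodes PD-1, at 62.6 and 4.48 CPM (-3.81, -4.00 to -3.61). Spp1 (-5.28), Il1r2 (-4.87), Gpm6b (-4.22), Spry1 (-4.08), Rgs16 (-4.05), Nrgn (-3.93) and Tox2 (-3.74) completed the 12 lowest. The 12 highest held the natural killer receptor genes Klra1 (2.32, 2.12 to 2.51), Klra7 (2.10), Klrc2 (2.04), Klrk1 (1.58), Klre1 (1.49) and Klrb1c (1.36), and the adaptor gene Fcer1g (2.01). Dapl1, high in naive T cells (1.62), Pdlim4 (1.70), Rcn3 (1.52), Arl4d (1.41) and G0s2 (1.4) made up the rest. Among the genes set in advance, Cd4 was at -1.92, Cd8a at 0.47, Foxp3 at -2.27, the lymph node homing receptor Sell at 0.65, the memory marker Cd44 at -0.41 and Ighm at -0.96.

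These sums mixed classes whose shares differed. Within the naive CD4 T-like class, 12 of the 24 named genes lay on the same side of a ratio of 1 as in the sum, and within the regulatory T-like class Foxp3 stood at 0.23. The median log2 ratio of all genes at 5 CPM or more was -0.22 in all T cells, -0.21 in the CD4 gate and -0.12 in the CD8 gate; the percentiles of gene lists are relative to genes of like expression, and their counts of members are relative to these medians. RNA make-up differed between the libraries. Gm42418, a gene that collects ribosomal RNA reads, took 1.62% of WT and 3.21% of KO T cell UMIs. It took 1.51% and 3.26% in the CD4 gate, 1.71% and 3.20% in the CD8 gate, and 1.65% and 3.27% in naive CD8 T-like cells. Cytosolic ribosomal protein genes took 30.4% and 37.1% of T cell UMIs. Their shares were closer within naive CD8 (40.2% and 41.6%) and memory CD8 T-like cells (36.8% and 37.3%), and 22.6% and 26.9% in regulatory T-like cells.

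In the CD4 gate, naive genes were higher and the exhaustion, follicular helper and regulatory lists lower in KO. Of 15 naive and quiescence genes measured, 13 lay above the median of all genes by the set margin and none below (list median 0.93, percentile 100 among 10000 matched random lists), among them Dapl1 (28.2 and 159 CPM, 2.5, 2.33 to 2.66), Actn1 (1.84), the chromatin organiser Satb1 (1.56) and Sell (1.28). All 14 measured exhaustion and age-associated genes were lower (median -1.80, percentile 0), with Lag3 at -5.46 (-6.07 to -4.90), Gzmk at -3.18, Pdcd1 at -3.02 and the transcription factor Eomes at -2.80. All 14 follicular helper genes were lower too (median -2.08, percentile 0), with Il21 at -5.39, Sostdc1 at -4.80, the homing receptor Cxcr5 at -2.40 and Bcl6, the master regulator of these cells, at -2.25. The regulatory list had 14 of 16 members lower (median -1.37, percentile 0), with Il10 at -2.51, Ctla4 at -1.51 and Foxp3 at -0.86 (-1.06 to -0.67).

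Other genes among the 12 lowest of the CD4 gate were the chemokines Ccl4 (-7.38, -9.66 to -5.83) and Ccl3 (-4.54), Ecel1 (-6.68), Spp1 (-4.67), Il1r2 (-4.26), Esm1 (-4.18), Cebpa (-3.88), Ptpn5 (-3.77) and Fam43a (-3.76). Besides naive genes, the highest were Pdlim4 (2.58), Myo6 (2.57), Ly6c1 (2.31), Vipr1 (1.96), the complement regulator Cd55 (1.89), Klrd1 (1.75), the cell cycle gene Ube2c (1.67), Prkd3 (1.53) and Hist1h2ab (1.51). Cd44 was at -0.71, Cd4 at -0.29 and Ighm at -1.44. On cells thinned to 1000 UMIs, 11.5% of WT and 1.60% of KO CD4 gate cells had a Pdcd1 UMI (33.1% and 5.90% unthinned). In naive CD8 T-like cells, which should lack it, the thinned shares were 0.155% and 0%. Median depth in that gate was 4673 UMIs in WT and 4735 in KO, and in the naive CD8 T-like class 7937 and 6504.

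In the CD8 gate, Gzmk and inhibitory receptor genes were again lower in KO. Gzmk stood at 138 CPM in WT and 8.49 in KO (-4.02, -4.19 to -3.86), Lag3 at -3.95, Pdcd1 at -3.53, the inhibitory receptor Tigit at -2.69 and Foxp3 at -2.38. A Foxp3 UMI was found in 0.752% of thinned WT and 0.116% of thinned KO cells of this gate, against 0.310% and 0.119% of naive CD8 T-like cells, so the KO share was at background. The exhaustion list had 11 of 12 measured members lower (median -1.51, percentile 0), and the cytotoxic list 13 of 18 (median -0.74, percentile 0), with Ccl3 (-2.26), Ccl4 (-2.02), Klrg1 (-2.02) and granzyme B, Gzmb (-1.90). Penk, which encodes proenkephalin (-5.30), Ier3 (-3.72), Maf (-3.31), Tnfrsf4 (-2.79), Hist1h1b (-2.6), Ly6a (-2.01) and the heat shock gene Hspa1a (-2) were also among the 12 lowest. The highest were Fcer1g (9.84 and 44.3 CPM, 2.17, 1.98 to 2.37), Klra1 (2.11), Klrc2 (1.57), Klra7 (1.57), Klrb1c (1.48), Klra6 (1.45), Fam177a (1.41), Actn1 (1.27), Dapl1 (1.15), Lars2 (1.11), Rcn3 (1.10) and Usp28 (1.06). Sell was at 0.16 in the gate, but at -0.14 within naive CD8 T-like cells; Cd8a was at -0.12 and Cd44 at -0.08 (-0.18 to 0.01). A Gzmk UMI was found in 13.3% of thinned WT and 0.774% of thinned KO CD8 gate cells (23.5% and 2.78% unthinned, at median depths of 7888.5 and 6926.5 UMIs), against 0% of thinned naive CD4 T-like cells in either library (median depths 5423 and 4735).

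Interferon response genes, which type I interferon induces, were lower in KO in each gate and in both naive classes. Over all T cells, 14 of 26 measured members lay below and 1 above the median of all genes (list median -0.64, percentile 0), with Ifi27l2a at -1.78, Oas1a at -1.59, Isg20 at -1.48 and Stat1, the signal transducer of interferon receptors, at -1.17. The list median was -0.54 in the CD4 and in the CD8 gate, -0.63 in naive CD8 T-like and -0.54 in naive CD4 T-like cells, all at percentile 0. Genes of MHC class I and antigen processing went the same way, with medians of -0.53, -0.50 and -0.42 in all T cells, the CD4 gate and the CD8 gate (percentiles 0, 0.07 and 0), with H2-T22 at -0.91, H2-Q4 at -0.82 and the peptide transporter Tap1 at -0.79. In naive CD8 T-like cells, Ly6a (-2.19, -2.34 to -2.04), Iigp1 (-1.83), St6galnac4 (-1.69), Stat1 (458 and 169 CPM, -1.44, -1.52 to -1.36) and Usp18 (-1.43) were the 5 lowest genes.

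Genes were also compared within classes, whose own make-up can differ between the libraries. In naive CD8 T-like cells the highest in KO were Pdlim4 (2.20), Camk2n1, a kinase inhibitor (2.09), Fam177a (1.67), Prss12 (1.44) and the fatty acid oxidation gene Cpt1a (1.35). In memory CD8 T-like cells the receptor genes Cd163l1 (1.81), Klrk1 (1.43) and Klrc2 (1.43) were higher, with Olfm1 (1.43) and Fam177a (1.35), and the heat shock genes Hspa1a (-2.30) and Hspa1b (-1.96) lower, with Nccrp1 (-1.88), Ly6a (-1.65) and Pltp (-1.64). In naive CD4 T-like cells Myo6 (1.65), Fam177a (1.64) and Ahnak (1.31) were higher, and the transcription factor Sox4 (-1.96), the cytokine receptor kinase Jak3 (-1.52) and Bcl3 (-1.30) lower. In memory CD4 T-like cells Dapl1 was at 1.37 and the T cell receptor adaptor Trat1 at 1.01, and Lag3 at -2.91, Sostdc1 at -2.46 and Serpina3g at -1.97. In cluster 2, the cytoskeletal gene Actn1 (1.84) and Trio (1.48) were higher and Nrarp, a Notch target (-1.42), and the phosphatase Dusp2 (-1.30) lower. The exhaustion list had medians of -0.49 in naive CD8, -0.68 in naive CD4 and -0.38 in memory CD4 T-like cells and -0.80 in cluster 2 (percentiles 0.08, 0.23, 0.16 and 0). In memory CD8 T-like cells its median of -0.20 lay within the random range (percentile 6.45). Lists of other cells were lower in some of these classes too: the B cell list stood at -0.69 in naive CD8 and -1 in memory CD4 T-like cells, and the follicular helper and cytotoxic lists at -0.55 and -0.61 in naive CD8 T-like cells. RNA from other WT cells was therefore not excluded as a source of these differences.

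**Figure D2:**
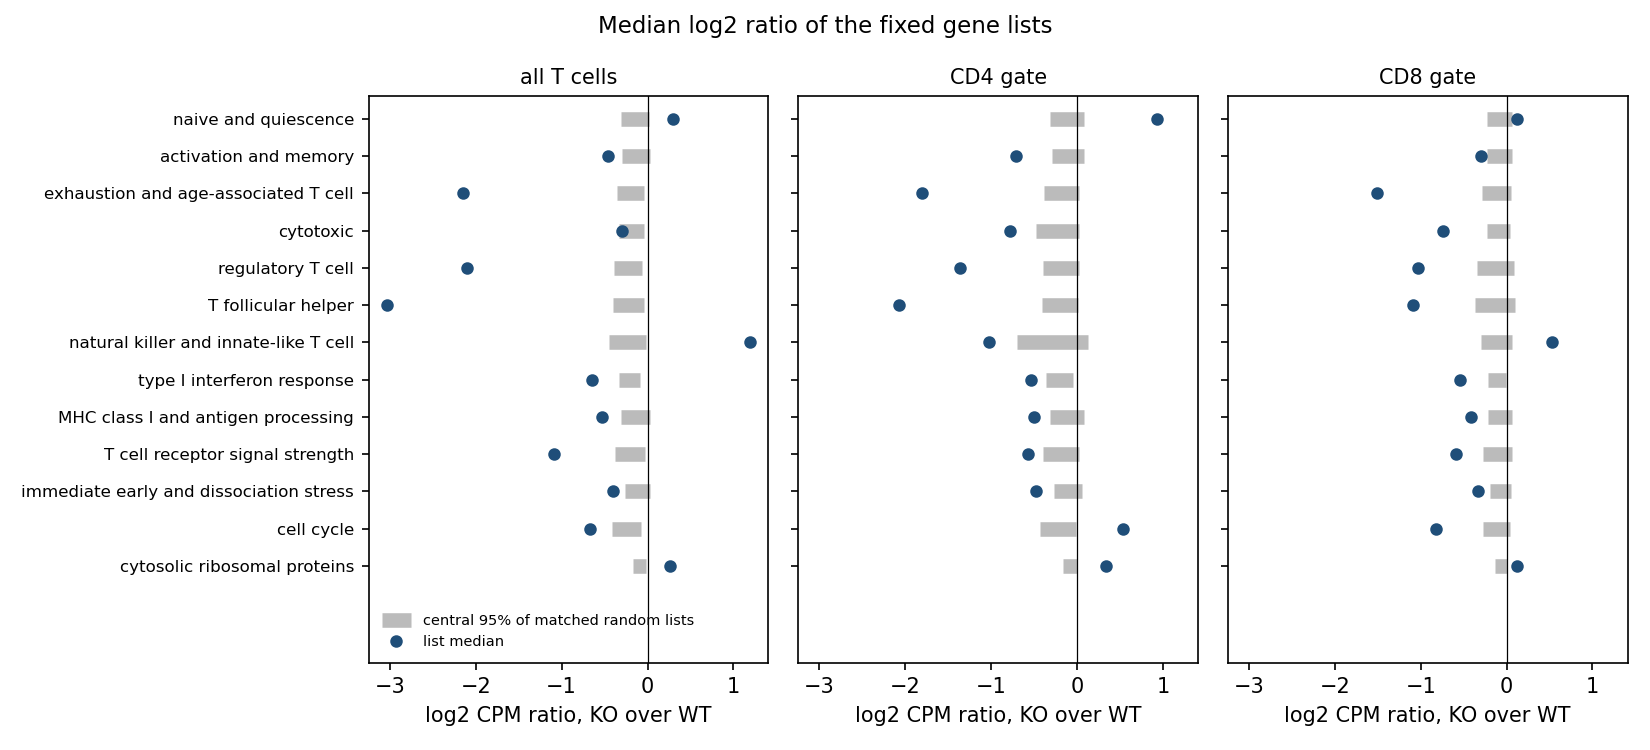
Median log2 ratio of CPM, KO over WT (horizontal axis), of 13 gene lists (vertical axis) in all T cells, the CD4 gate and the CD8 gate; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. The exhaustion list lies left of its bar in each panel (-2.15, -1.80 and -1.51), and the natural killer list lies left of it in the CD4 gate (-1.02) and right of it in the CD8 gate (0.53).

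In all T cells the exhaustion list had a median of -2.15, the follicular helper list -3.03 and the regulatory list -2.10 (all percentile 0), and the naive list 0.30 (percentile 100). In the CD8 gate the follicular helper, regulatory and naive lists had medians of -1.08, -1.03 (both percentile 0) and 0.12 (percentile 99.8). Activation and memory genes were lower, with medians of -0.46 in all T cells, -0.71 in the CD4 gate and -0.30 in the CD8 gate (percentiles 0.05, 0 and 0.2); S100a4 (-1.62) and the integrin gene Itgb1 (-1.24) led the list in all T cells. Within classes it was not lower in memory CD8 (0.04, percentile 92.8), memory CD4 (0.02, percentile 79.9) or regulatory T-like cells (0.20, percentile 99.5), nor in cluster 5 (0.53, percentile 100). Cytokines and chemokines had medians of -1.40, -1.50 and -0.65 (all percentile 0), with Tnfsf11 at -2.70 and Il10 at -4.27 in all T cells. Genes that follow receptor signal strength had medians of -1.09, -0.57 and -0.58 (percentiles 0, 0.08 and 0), led by Egr2 (-2.44) and Irf4 (-2.14). Immediate early and stress genes had medians of -0.40, -0.48 and -0.33 (all percentile 0), with Hspa1a (-2.86) and Dusp1 (-1.11). Glycolysis genes had medians of -0.43, -0.55 and -0.33 (percentiles 0.22, 0.01 and 0.05), with Pkm at -0.97. Cytotoxic genes had medians of -0.30 in all T cells (percentile 6.63) and -0.78 in the CD4 gate (percentile 0).

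The natural killer and innate-like list had medians of 1.20 in all T cells (percentile 100), -1.02 in the CD4 gate (percentile 0.21) and 0.53 in the CD8 gate (percentile 100). Cell cycle genes had medians of -0.67, 0.54 and -0.83 (percentiles 0.01, 100 and 0). Senescence and inflammation genes had medians of -0.50, -0.36 and -0.19 (percentiles 0.04, 3.89 and 11.2), with the cell cycle inhibitor Cdkn1a at -1.57 and Tnf at -1.46 in all T cells. Type 1 helper genes had medians of -0.10, -0.56 and -0.18 (percentiles 83.2, 0.51 and 18.4), and homing receptor genes -0.41, -0.36 and -0.19 (percentiles 0.65, 4.42 and 9.53). The type 17 and gamma-delta list had a median of 0.33 in all T cells (percentile 99.7, 5 members) and -0.18 in the CD8 gate (percentile 46.4), and the first of these turned to -0.77 when genes down to 1 CPM were taken in. Nuclear-encoded oxidative phosphorylation genes lay within the random range (-0.11, -0.07 and -0.11; percentiles 84.6, 94.3 and 21.4). Ribosomal protein genes were higher (0.27, 0.34 and 0.12, all percentile 100), as were mitochondrially encoded genes (0.23, 0.18 and 0.27; percentiles 99.5, 98.0 and 100).

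Markers of cells outside the sort were also measured. The B cell list had medians of -1.77, -1.17 and -1.37 (percentiles 0.03, 0.15 and 0.01) on 4 or 5 measured genes, with Igkc at 62.5 CPM in WT and 1.41 CPM in KO T cells. Of all T cells and the gates, only the CD4 gate had enough plasma cell genes for a median (3 genes, -1.85, percentile 0.1). Monocyte and macrophage genes (-0.16, -0.23 and 0.03; percentiles 56.7, 32.8 and 83.4) and dendritic cell genes (0.06, -0.30 and -0.27; percentiles 95.7, 41.2 and 17.7) lay within the random range. Neutrophil, erythroid and platelet genes had 0 measured members in all T cells and in either gate. Of the sex-linked genes, Xist stood at 291 CPM in WT and 293 CPM in KO kept cells, and Ddx3y and Eif2s3y had 0 UMIs in both.

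Clonal expansion was lower in the KO library. At 5987 cells from each library, 34.8% (33.6 to 36.1) of WT and 10.2% (9.48 to 11) of KO cells with a TRB chain belonged to clonotypes of 2 or more cells. Clonotypes of 5 or more cells held 17.3% (16.4 to 18.3) of WT and 4.26% (3.76 to 4.8) of KO cells, and the 10 largest clonotypes 7.21% and 2.86%. The Gini index, which is 0 when every clonotype has the same size, was 0.247 and 0.0713, and the normalized Shannon entropy was 0.958 and 0.990. By TRB chain alone, 39.6% of WT and 14.1% of KO cells were in clonotypes of 2 or more. Only 64.0% of KO cells with a TRB chain also had a TRA chain, against 86.5% in WT; with both chains required the shares were 33.5% and 11.7%.

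Expansion was lower in the KO library in both gates and in memory CD8 T-like cells. The share depends on the number of cells drawn, so values of different classes are not on the same scale. When 738 cells of each CD4 gate were drawn, 17.6% (14.9 to 20.6) of WT and 6.1% (4.48 to 8.07) of KO cells shared a clonotype; over all cells, 37.6% and 7.86% belonged to clonotypes of 2 or more in the library. For 2632 cells of each CD8 gate the shares were 38.8% (37 to 40.7) and 9.10% (8.01 to 10.2). Memory CD8 T-like cells had 54.4% (51.4 to 57.4) in WT and 20.7% (18.3 to 23.2) in KO at equal numbers. By TRB chain alone, the drawn shares of these cells were 56.7% and 28.1%. They were 42.1% and 12.8% in the CD8 gate and 20.3% and 7.05% in the CD4 gate. Memory CD4 T-like cells (12.4%, 8.26 to 18.2, and 16.8%, 11.8 to 22.9) and regulatory T-like cells (9.84%, 5.55 to 15.6, and 7.14%, 3.62 to 12.4) had overlapping intervals in these draws. Over all cells, where WT had more, the intervals did not overlap. The shares were 34.0% (30.7 to 37.4) and 18.9% (13.6 to 25.3) in memory CD4 T-like cells. In regulatory T-like cells they were 32.2% (29.3 to 35.1) and 9.74% (5.55 to 15.6). All expansion intervals take cells as independent, although cells of a clone enter a share together, so they can be too narrow. In draws from cluster 5, as in draws of 23 follicular helper T-like cells (2.96%, 0.110 to 21.9, and 8.70%, 1.07 to 28.0), the order was the other way, with 22.7% (16.2 to 31.0) in WT and 39.3% (31.0 to 48.0) in KO, on 135 cells each. Over all cells of cluster 5, 995 in WT and 135 in KO, the shares were 50.8% (47.6 to 53.9) and 43.7% (35.2 to 52.5), so the order depended on the draw. By TRB chain alone the drawn shares of cluster 5 were 26.6% (19.4 to 35.0) and 64.4% (55.8 to 72.5). Over all its cells they were 60.9% (57.8 to 64.0) and 68.9% (60.4 to 76.6). In cluster 2 the shares at 168 cells each were 10.1% and 3.02%, or 11.3% and 5.36% by TRB chain alone. Over all its cells, 168 in WT and 1131 in KO, they were 13.1% (8.39 to 19.2) and 13.7% (11.8 to 15.8). By TRB chain alone they were 17.3% and 19.5% over all cells. Naive CD8 T-like cells had 1.73% and 0%, and naive CD4 T-like cells 0.416% and 0.299%.

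**Figure D3:**
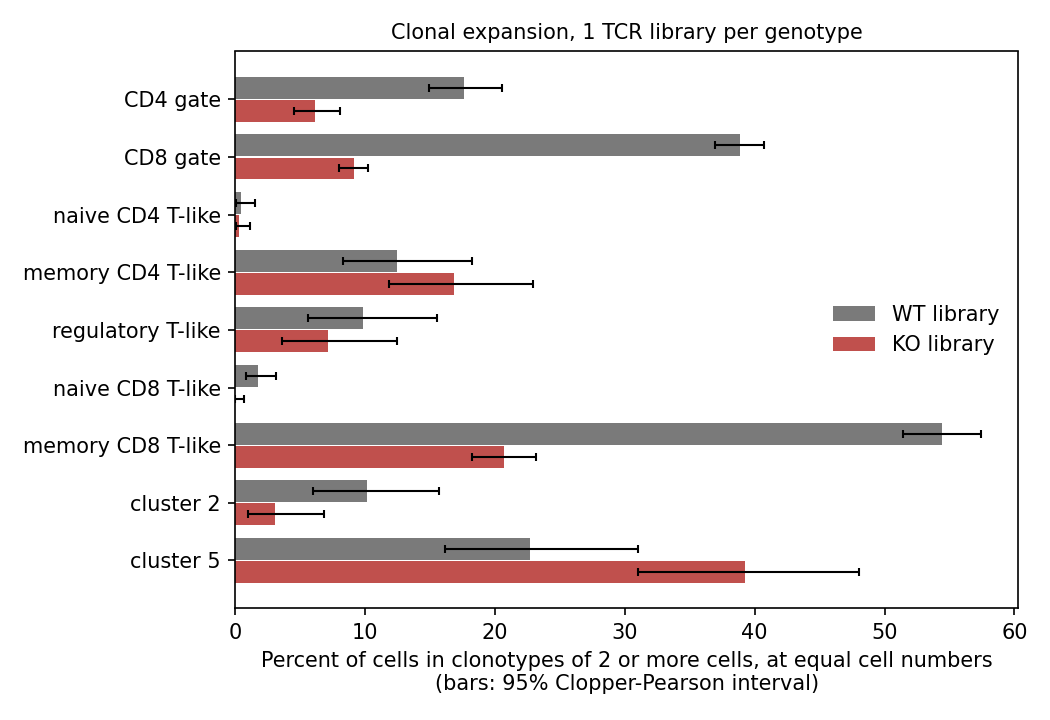
Percent of cells that share a clonotype with another drawn cell (horizontal axis), at equal cell numbers per genotype, by gate, class or unnamed cluster (vertical axis), with 95% Clopper-Pearson intervals as error bars. The memory CD8 T-like bars stand at 54.4% in WT (grey) and 20.7% in KO (red), and the cluster 5 bars at 22.7% and 39.3%.

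Use of receptor gene segments also differed. Over clonotypes, 5 of 20 TRBV genes with a share of 1% or more differed by at least 1.5 times, against 10 of 22 over cells. TRBV2 was 5.81% (5.15 to 6.53) of WT and 1.49% (1.18 to 1.86) of KO clonotypes, and TRBV19 7.58% (6.83 to 8.39) and 2.75% (2.31 to 3.23). TRBV12-1 was 3.42% and 6.51%, TRBV12-2 2.78% and 6.53%, and TRBV17 1.73% and 3%. TRBV12-1 and TRBV12-2 are close paralogs, and telling them apart rests on the authors' assignment. Chains with the joint call TRBV12-2+TRBV13-2 were found in both libraries and were counted apart from TRBV12-2. For TRAV genes, 28 of 49 differed over cells and 29 of 53 over clonotypes, for example TRAV6N-6 (1.34% of WT and 0.114% of KO clonotypes, and 2.49% and 0.105% of cells) and TRAV12-2 (2.60% and 4.94% of clonotypes). This family holds many near-identical copies. The invariant TRAV11-TRAJ18 chain of natural killer T cells was found in 76 of 6438 WT (1.18%, 0.931 to 1.48) and 26 of 4113 KO cells with a TRA chain (0.632%, 0.413 to 0.925), of which 66 and 20 lay in the natural killer T-like class. The TRAV1-TRAJ33 chain of mucosal-associated invariant T cells was found in 1 and 5 cells. Mean TRB CDR3 length was 13.9 residues over clonotypes in both libraries (SD over clonotypes 1.42 and 1.43).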

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

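No test was chosen for this part after the results were seen; the lists were fixed beforehand, and the differences between gates were not tested. The natural killer and innate-like list went opposite ways in the gates, with a median log2 ratio (KO over WT) of -1.02 in the CD4 gate and 0.53 in the CD8 gate. In the CD4 gate Eomes (-2.80), Il2rb (-1.27) and Xcl1 (-1.24) were lower, while in the CD8 gate Fcer1g (2.17) and Klra1 (2.11) were higher and Klra8 (-1.49) lower. The list also differed between classes with CD8 gate cells: its median was -0.86 in naive CD8 T-like cells (percentile 0.01), -0.23 in cluster 2 (percentile 0.95), 0.09 in memory CD8 T-like cells (percentile 91.7) and 2.14 in cluster 5 (percentile 100). Clusters 2 and 5 are mixed: 54.5% of WT and 67% of KO cells of cluster 2 were in the CD8 gate and 44.5% and 30.5% had no Cd4, Cd8a or Cd8b1 UMI, and cluster 5 held 17.8% and 10.7% CD4 gate cells. Cluster 2, led by such genes, was 3.64% of the WT and 18% of the KO CD8 gate. The cell cycle list also went opposite ways, with 0.54 in the CD4 gate, where Cenpf (1.70) and Birc5 (1.27) were higher, and -0.83 in the CD8 gate, where Rrm2 (-1.75) and Pclaf (-1.68) were lower. Regulatory, naive CD4 and memory CD4 T-like cells did not show the higher cell cycle list, with medians of -0.62 (percentile 0.23), -0.04 and -0.02. Cycling T-like cells were 18 of 3229 cells of the WT CD4 gate (0.557%, 0.331 to 0.880) and 8 of 949 of the KO CD4 gate (0.843%, 0.365 to 1.65), and 1.46% and 0.514% of the CD8 gates. Cells outside the T cell comparisons held a further difference: myeloid-like cells, led by the complement genes C1qa, C1qb and C1qc, were 1.08% (0.872 to 1.31) of kept WT cells and 3.54% (3.15 to 3.97) of kept KO cells, although the sort was on CD3. Over both libraries, 30.3% of these cells had a TRB chain and 53.4% a Cd3e UMI. No doublet had been removed, so doublets with T cells were not told apart from single myeloid-like cells.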

How the results depend on the processing

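Leaving out cells with more than 1 TRB chain, leaving out clusters 8 and 15, keeping only cells with a TRA chain, and the value over all cells for expansion by lineage were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each genotype had 1 library of a kind and no test was run, and leaving out a replicate was not possible for the same reason. Keeping Scrublet doublets was not run, since none was called. Of the alternative values of the main results, 118 stayed within counting error or, for counts, within 1.5 times, and 31 moved. The moved gaps in shares and in expansion kept their direction. The other moved values were 7 counts of named genes and 1 count of TRBV genes, which have no direction. Among these counts, only 12 of the 24 genes named in all T cells kept their side within naive CD4 T-like cells. The cause of each move was not tested unless given.

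The CD4 gate gap (KO minus WT, percentage points) was -24.9, and -27.3 in cells with a TRB chain, -11.9 after thinning to 1000 UMIs (fewer cells then show a Cd4 UMI) and -28.0 with gates by Cd4 alone and Cd8b1 alone; the CD8 gate gap of 31.2 became 32.8, 20.4 and 26.4. Memory CD8 T-like cells went from 3.65 to 0.801 at Leiden resolution 1.4, 2.004 with 4000 variable genes and 2.43 without cells with more than 1 TRB chain. With values centred per library, naive CD4 T-like cells went from 7.21 to 5.64 and regulatory T-like cells from -12.0 to -10.6. Memory CD4 T-like cells went from -8.53 to -7.48 at resolution 1.4; at resolution 0.6, with centring and with 4000 variable genes no cluster took that name, so there is no value. Follicular helper T-like cells went from -14.9 to -16.1 in cells with a TRB chain, -23.5 at resolution 0.6, -16.0 at resolution 1.4, -19.7 with centring and -22.5 with 4000 variable genes. At resolution 0.6, with centring and with 4000 variable genes, cells of the memory CD4 T-like class fell under other names. These follicular helper values may therefore include them.

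Of the 24 named genes, a filter of 10 CPM in both libraries left 8 in all T cells, 8 in the CD4 gate and 11 in the CD8 gate, and no filter 2, 5 and 1, since the filter decides which genes can be named. Within naive CD4 T-like cells, 12 of the 24 genes of all T cells kept their side. Within naive CD8 T-like cells Cd4 (1.70), Cd8a (-0.26) and Sell (-0.14, all T cells and the CD8 gate) took the opposite sign to the sums, as did Foxp3 within regulatory T-like cells (0.23, all T cells and the CD4 gate) and Satb1 within naive CD4 T-like cells (-0.10); these compare 1 class in place of a mixture. The type 17 and gamma-delta list in all T cells turned to -0.77 at a mean of 1 CPM or more. Of the other values for single genes, 615 stayed within counting error and 379 moved. A moved value could change sign where an interval held 0, as for genes within naive CD4 T-like cells. Of the values for single lists, 684 stayed, 10 moved out of the random range and 14 into it. TMM and median-of-ratios factors brought the median of all genes in all T cells from -0.22 to 0.00 and 0.01.

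The expansion gap of -24.6 points was -21.8 with the same TRA and TRB CDR3, -26.5 over all cells, -18.1 for 3 or more cells and -21.2 in cells with a TRA chain. In the CD4 gate the gap of -11.5 became -26.6 over all cells with clonotype sizes counted within the gate, where WT had more cells. It was -15.4 in the named CD4 classes pooled together, which is not a gap within classes. TRBV genes named fell from 10 to 5 per clonotype. Depth limits the smallest classes: with 23 follicular helper T-like cells with a TRB chain in KO, expansion over all cells was 52.4% in WT and 30.4% (13.2 to 52.9) in KO, but 2.96% (0.110 to 21.9) and 8.70% (1.07 to 28.0) in draws of 23.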

Other observations

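The tests of uneven TRBV recovery and of an interferon-responding subset were chosen before their results were seen; all other tests in this part were chosen afterwards. The rule that reads a value against its bounds was also altered after results were seen. As used, it excludes an explanation as the whole cause when the spread lies beyond the bound that explanation needs, and under the first rule uneven TRBV recovery had stayed undecided. Brackets of the tested values are not exact intervals. For the set of TRBV segments they are medians of the segments' bounds. For TRA chains and Trac they span approximate standard errors on either side, and for interferon genes they come from resampling the genes. The cells of cluster 5 differed between the libraries in the lists they expressed. Gzma, which encodes granzyme A, was at 82.2 CPM in WT and 692 CPM in KO cells of the cluster (log2 ratio 3.07, 2.92 to 3.23), and Lgals3 (2.18), Cd226 (2.14), Klra7 (1.95) and Klre1 (1.85) were higher too. The natural killer list had a median of 2.14 and the cytotoxic list of 1 (both percentile 100), while the exhaustion list had -0.90 and the follicular helper list -0.95 (both percentile 0). The cluster held 17.8% CD4 gate and 55.8% CD8 gate cells in WT, and 10.7% and 63.1% in KO. In regulatory T-like cells, Klrg1, a receptor of effector cells, was higher in KO (48.8 and 133 CPM, 1.45, 1.14 to 1.75), as was Ccr6 (1.36). Sostdc1 (-6.11, -9.16 to -4.25) was lower, and the exhaustion list had a median of -0.96 (percentile 0).

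Clones in this paragraph are cells with the same TRB chain, not the submitters' clonotypes. Cells in clones of 5 or more numbered 1506 in WT and 365 in KO among T cells with expression data. Of these, 56.3% (53.8 to 58.8) of WT and 88.2% (84.5 to 91.3) of KO cells were in the CD8 gate, and 30.7% and 6.58% in the CD4 gate. Among all T cells with a TRB chain, the CD8 gate held 2632 of 7056 in WT and 4113 of 5869 in KO. The CD4 gate held 2817 and 738. The CD8 gate was thus already the larger share of such cells in KO. Follicular helper T-like and memory CD4 T-like cells of WT shared 64 clones (9.88% of 648 memory CD4 T-like clones). Those of KO shared 4 (18.2% of 22 follicular helper clones). Memory CD8 T-like cells and cluster 2 shared 39 in KO (4.36% of 894 memory CD8 T-like clones). In WT they shared 4 (2.55% of 157 cluster 2 clones). Each percentage is of the smaller set, which was not the same class in both libraries. Of the TRB chains, 22 were found in both libraries, out of 4913 in WT and 5376 in KO.

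The 5 TRBV segments that differed over clonotypes also differed in the expression libraries, in the same directions. As log2 ratios of their share of all Trbv UMIs, TRBV12-1 stood at 0.82 (0.74 to 0.89), TRBV12-2 at 0.62, TRBV17 at 0.50, TRBV19 at -0.60 and TRBV2 at -0.94 (-1.05 to -0.82). The median signed difference was 0.617 (0.553 to 0.680), 59.1% of the 1.04 in contigs counted over cells. That argues against uneven recovery in the receptor library as the whole cause and leaves a part of it open. The shares over clonotypes, from which the 5 segments were chosen, count each TRB chain once, so clone size does not enter those. The values tested here count cells or UMIs, so clone size can enter them. Another mix of classes would have left little in naive CD8 T-like cells, but the 5 segments kept 1.36 (0.511 to 1.97) as a set, though TRBV12-1 (0.36) and TRBV17 (0.09) differed less there than over all cells. Genotype itself, or the mice behind each library, may also differ in segment use, and that was not tested.

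Fewer KO cells with a TRB chain had a TRA chain (64.1% against 86.7% among T cells). With WT class weights 17.7 points (14.5 to 20.8) of the gap of 22.6 remained, which argues against the mix of classes as the whole cause. Lower Trac expression would need a log2 ratio of Trac to Trbc UMIs near the -0.45 of the chains, but it was -0.14 (-0.19 to -0.10); that lies just inside the bound set for a smaller effect, by less than its spread. A lower yield of TRA chains in the KO receptor library may remain, and it was not tested; clonotypes of the KO library rest on fewer TRA chains as a result, and 41.7% of its TRB chains with 2 or more cells were split over several clonotypes, against 24.8% in WT.

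Interferon response genes were lower in naive CD8 T-like cells of the KO library (list median -0.63). Without the 10% of cells with the highest share of these genes in each library the median was -0.69 (-0.99 to -0.39), which argues against a small subset of responding cells. Free RNA from other cells of the WT spleen would add like amounts to every class; the WT minus KO difference in memory CD8 T-like cells was 0.437 times that in naive CD8 T-like cells (median of 23 genes, quartiles 0.251 and 0.689), between the bounds, so this source and a difference within the naive cells cannot be told apart. Stat1 stood at 458 CPM in WT and 169 CPM in KO naive cells, and at 121 and 82.7 CPM in memory cells. An effect of genotype was not tested.

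DNA of another strain around the targeted Ighm locus might alter neighbouring genes in the KO. The median absolute log2 ratio of 46 genes within 10 Mb was 0.216 in naive CD8 T-like cells (percentile 81.6; random range 0.130 to 0.253), which argues against a shift of these genes as a set; a few changed genes would not move the median and were not tested singly.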
